A study of Mus musculus with 6 samples.

How the data were processed

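The series holds 6 expression arrays from mouse cells, 3 from cells given control miRNA and 3 from cells given miR-34c. Per the labels, the cells were tumour lines from mice in which Dicer and Pten had been deleted in the female reproductive tract. Groups and replicate numbers were taken from the sample titles. Total RNA was isolated on spin columns and labelled with biotin, per the labels' protocols.

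Each array came with the values of 45281 probes on an Illumina bead array. The authors deposited, for each probe, an average signal intensity on a linear scale with no normalization seen in the values. They also deposited a detection p-value and the number of beads behind each intensity. A deposited table of the whole series held a further intensity per probe and array, normalized by the authors. In that table every array had a median of 79.7 and a maximum of 33365.4, and the column of control replicate 1 equalled its unnormalized intensities. The table is therefore on a linear scale with each array set to the distribution of control replicate 1. The software behind it, and the scanner software, are not given in the sources used here.

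The unnormalized intensities carried a numeric probe number and the normalized table an Illumina identifier. On each array the sorted unnormalized intensities were set against the sorted normalized ones, and a probe was then matched by its values on the 6 arrays together, which matched all 45281 probes. With 1 array withheld at a time, 271686 of 271686 matches gave the right value to 2 decimals. Gene symbols came from GEO's platform annotation and were compared by Entrez identifier with a RefSeq gene table of the assembly GRCm38.p6, used for names only. There were 34885 probes with 1 symbol, 18 with several and 10378 without a symbol in that annotation. Of those with 1 symbol, 34807 were matched by identifier and 0 symbols had to be updated. The named probes stood for 19057 genes, and probes with several symbols or none were left out of the gene comparison.

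Background correction and normalization used neqc in limma 3.58.1 under R 4.3.3, which takes the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was tested where its detection p-value was under 0.05 on at least 3 of the 6 arrays, whichever these were. A gene was represented by its tested probe with the highest mean over all arrays. This left 14737 probes and 8745 genes. Among 2969 genes with several tested probes, 644 had a probe whose difference had the opposite sign. The groups were compared with lmFit and eBayes in limma, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are miR-34c minus control throughout, and adjusted p-values are limma's. Where a probe was above background on no array of a group, the fold is a lower bound against the lowest signal among detected probes of each array.

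The linear model held the group and no block, since the labels name none. Both groups share the replicate numbers 1 to 3, so a fit with the number as a block was an alternative. Deviations from the group means correlated across genes at 0.69, 0.61 and 0.75 between samples of the same number, and between -0.55 and -0.10 otherwise. The array names in the deposited files also share a number within each such pair. The numbers were therefore taken to pair the samples, although the labels do not say whether a pair is 1 tumour line. The value with the block is printed wherever it changes a call or moves a count by over 1.5 times.

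Gene lists written from textbook knowledge were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 25 lists. Camera with an estimated correlation and fry were run beside it. The lists covered reported miR-34 targets, G1/S and DNA replication, G2/M and mitosis, DNA damage repair, p53 targets, apoptosis regulators, interferon response, NF-kB and inflammatory cytokines. Others held epithelial and serous tumour, mesenchymal, smooth muscle, immune and endothelial markers, and miRNA processing. The rest were PI3K, Notch, Wnt and TGF-beta signalling, the unfolded protein and integrated stress response, glycolysis, cholesterol synthesis, hypoxia targets, ribosomal proteins, imprinted and let-7 fetal genes, and senescence. A list of ovarian steroidogenic and granulosa markers was not tested, because fewer than 3 of its genes passed the detection filter. Members shared between lists count in each.

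Genes were named by a rule. It took Dicer1 and Pten, the 12 genes with the largest rise and the 12 with the largest fall among those called and of 1 sign in all 3 pairs, up to 4 members per list with the smallest p in the fit with the block, and any reported miR-34 target. Some members that fit this rule are left out of the text for length. Among the genes named outside it are Brip1, Birc2, Ifit3, Fn1 and Cdkn1a, and genes of the later cilium, lysosome and histone lists. The groups, the tests, this rule, the lists and the alternatives were fixed before the data were examined. The alternatives were each array left out, each pair left out with the block, no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' normalized table, no detection filter, detection on all 6 arrays, the mean of all probes of a gene, eBayes with trend and robust settings, array weights, other thresholds and a plain t-test. A planned search for miR-34c sites in 3' UTRs was not run, because no transcript sequences were used here.

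The procedure was tested on simulated data with 200 changed genes among 8745 and the pair structure of these arrays. Without the block it recovered 3% of changes of 1 on the log2 scale and 80% of changes of 2, with 0 false calls among 83. With the block it recovered 93% and 100%, with 12 false calls among 205. More genes were called in the data, which makes the adjusted threshold less strict, so these shares need not hold there. The list test called the 1 simulated list that had been moved and 0 of the others. Those lists were random genes with independent noise, so they do not test the preset correlation on lists whose members move together. The estimated correlation was 0.0060 for reported miR-34 targets, 0.21 for G1/S and DNA replication, 0.35 for G2/M and mitosis and 0.68 for interferon response. The number of arrays limits the precision of every value. The labels call the samples biological replicates without saying whether these were separate lines or separate cultures, so the p-values measure the spread between these samples. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.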

Results

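Gene expression was measured on 6 Illumina mouse arrays in cell lines from serous epithelial tumours of Dicer and Pten double-knockout mice. Dicer cuts precursor hairpins into mature miRNAs, and Pten is a lipid phosphatase that restrains PI3K signalling. The lines had been transfected with miR-34c, a miRNA of the p53-induced miR-34 family, or with a control miRNA, with 3 samples in each group. The comparison asks which transcripts change when miR-34c is put into these tumour cells. Each array reported between 31.1% and 35.6% of its probes above background. Control replicate 1 was the brightest array, with a mean raw intensity of 263.9, against 197.5 to 208.9 on the others. The median number of beads per probe was 42 to 44.

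The deleted genes were examined in every sample. Dicer1 (Entrez gene 192119) had log2 intensities of 5.26, 5.49 and 5.46 in the control samples and 5.18, 5.11 and 4.80 in the miR-34c samples, close to background, and was detected on 5 of the 6 arrays. The difference of -0.37 (SE 0.18) did not pass the test (adjusted p = 0.236). Where its 3 probes lie relative to the deleted part is not given in the sources used here, so these values do not check the deletion. Pten was not analysed here, since no probe carried its symbol in the annotation used.

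Transfection with miR-34c was followed by changes in 969 of 8745 genes, 443 higher and 526 lower. With the replicate number as a block 2721 changed, 1414 higher and 1307 lower. A gene not called without the block can still have changed, since that fit recovered 3% of simulated changes of 1 on the log2 scale. That simulation changed 200 genes, fewer than were called here, which made its adjusted threshold stricter. The 3% is therefore not the recovery in these data. The largest rise was in Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases (Entrez gene 12577), from a log2 intensity of 6.42 ± 0.20 to 10.12 ± 0.32 (SD, n = 3 per group), or 12.9-fold. The largest fall was in Mcm5, a subunit of the replicative helicase (Entrez gene 17218), from 11.33 ± 0.16 to 7.79 ± 0.62 (SD, n = 3 per group), or 11.6-fold. Their log2 fold changes were 3.69 (SE 0.22, adjusted p = 0.00404) and -3.54 (SE 0.32, adjusted p = 0.011). Of the 969 genes, 292 rose and 371 fell by more than 2-fold (528 and 519 with the replicate number as a block), and their median absolute log2 fold change was 1.17.

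Among the 12 genes with the largest rises were genes of cilia and of the lysosome. Drc3, a regulatory subunit of motile cilia, rose 10.8-fold (adjusted p = 0.00404) and was above background on 2 of 3 control arrays. Its log2 fold change of 3.43 ran from 1.95 to 3.68 over the alternatives. Ctsl, the lysosomal protease cathepsin L, rose 9.42-fold (SE 0.41 on the log2 scale, adjusted p = 0.0121) and was above background on 1 of 3 control arrays. Its log2 fold change of 3.24 ran from 1.97 to 3.60 over the alternatives. Tmod1, which caps actin filaments, rose 9.33-fold (adjusted p = 0.0317) and was above background on 1 of 3 control arrays. Aoc1, which degrades histamine, rose 8.96-fold (adjusted p = 0.0142) and Fbxo36 8.74-fold (adjusted p = 0.011). Nme5 was not above background on any control array and was at least 5.49-fold higher with miR-34c (adjusted p = 0.00507). The thrombin receptor gene F2r rose 6.84-fold (adjusted p = 0.0183) and the glutamate transporter gene Slc1a2 7.37-fold (adjusted p = 0.0363). Mrvi1, Ccdc181 and Prss35 rose 7.38-fold, 6.76-fold and 6.67-fold. Slc1a2 and Prss35 were above background on 2 of 3 control arrays. Over the alternatives the log2 fold changes of Tmod1, Slc1a2 and Prss35 went down to 1.95, 1.89 and 1.73. The calls of Tmod1, Slc1a2 and Mrvi1 were lost with no detection filter, and those of Tmod1 and Slc1a2 also with other background corrections (adjusted p up to 0.115 for Tmod1 and 0.124 for Slc1a2 over all alternatives).

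The 12 largest falls held genes of chromosomes and the nucleus beside Mcm5. Cdca8, a component of the chromosomal passenger complex, fell 5.58-fold (log2 fold change -2.48, SE 0.38, adjusted p = 0.0148). The histone genes H2ac11 and H2ac12 fell 5.12-fold and 4.88-fold, and Lmnb2, a lamin of the nuclear envelope, 5.04-fold (adjusted p = 0.0185). Anp32a fell 5.38-fold, and Rbmx and Rbm38, which encode RNA-binding proteins, 5.18-fold and 4.94-fold. Zcchc3 fell 6.39-fold, Scamp4 5.14-fold and Gltp, above background on 2 of 3 miR-34c arrays, 4.99-fold. Snai3, of the Snail family of repressors, fell 5.31-fold and was above background on 1 of 3 miR-34c arrays.

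The 6 samples parted by group along the first principal component, which held 41.3% of the variance, and the second, with 34.8%, ordered the replicate numbers alike in both groups. With the replicate number as a block 2721 genes changed, 1414 higher and 1307 lower, and these included all 969. The gene count without the block, and with it each count of called list members, rested on control replicate 2, without which 1 gene, Drc3, still passed the test. Each other array left out in turn gave 506 genes without control replicate 1, 285 without control replicate 3, and 277, 485 and 362 without miR-34c replicates 1, 2 and 3. With the block, 1661 to 2158 genes passed when any pair was left out, and the 24 genes with the largest changes passed each time. These 24 had been picked on the same arrays for their call and for 1 sign in all pairs.

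**Figure D1:**
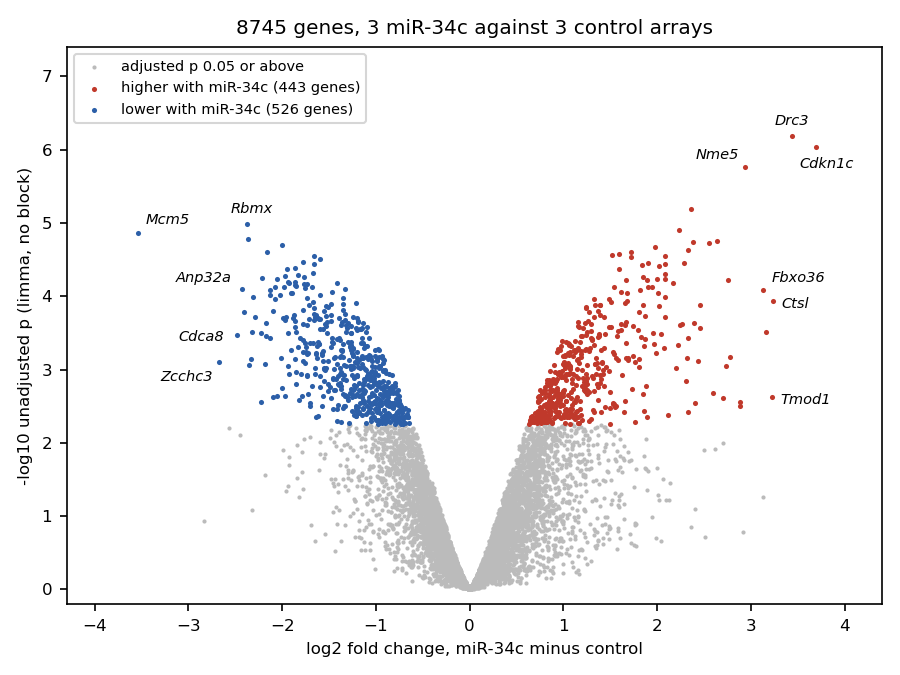
Log2 fold change (miR-34c minus control, horizontal axis) against minus log10 of the unadjusted limma p (vertical axis) for the 8745 genes tested, 1 point per gene. Coloured points are the 443 genes that rose and the 526 that fell at an adjusted p under 0.05, with Cdkn1c and Drc3 at the far right and Mcm5 at the far left.

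Agreement between pairs was seen across genes. In 5378 genes, or 61.5% of those tested, miR-34c minus control had the same sign in all 3 same-numbered pairs, where chance would give 25%. The sign was positive in 2707 genes and negative in 2671. Across genes, which are not independent replicates, the differences of any 2 pairs correlated at a Pearson r of 0.71 to 0.74. All 969 changed genes had 1 sign in the 3 pairs, which largely follows from their call on the same arrays.

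Of 26 messenger RNAs that earlier work reported as targets of the miR-34 family, 11 fell and 0 rose, adjusted over the list alone 13 fell, and with the replicate block 15 fell and 2 rose. Their mean log2 fold change was -0.68 (camera adjusted p = 3.11e-05, and adjusted p = 0.222 with an estimated correlation). The list held 50 genes, 46 of them on the array, and 11 of the 26 tested also stood in another list. Its camera call held without members shared with another list. Whether these genes fell as direct targets was not tested. Those that fell included Ccne2, which encodes cyclin E2, down 3.65-fold (log2 fold change -1.87, SE 0.32, adjusted p = 0.0183), and the cell cycle phosphatase gene Cdc25a, down 2.89-fold (-1.53, SE 0.20, adjusted p = 0.0123). The receptor tyrosine kinase gene Axl fell 2.22-fold, from 12.34 ± 0.06 to 11.18 ± 0.20 (SD, n = 3 per group), and Ldha, for lactate dehydrogenase A, 2.61-fold. Met, the receptor of hepatocyte growth factor, was above background on every control array and no miR-34c array, at least 1.22-fold lower (adjusted p = 0.0341).

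The other targets that fell were Cdc25c (log2 fold change -1.71), the E2F factor gene E2f5 (-1.64), the chromatin gene Mta2 (-1.45), Tpd52 (-1.40), Arhgap1 (-1.28) and the raft protein gene Flot2 (-1.10). Cdc25c was above background on 2 of 3 miR-34c arrays. The call of E2f5 was lost in 11 of 20 alternatives, including each other background correction and normalization (adjusted p up to 0.126). Median scaling also ended the calls of Mta2 and Met, leaving out pair 3 with the block that of Met, no detection filter those of Cdc25c and Flot2, and the mean over probes that of Axl. Called with the block alone, and above background on 2 of 3 miR-34c arrays except for Ccnd1, were Ccnd1, for cyclin D1, at -1.65 (adjusted p = 0.425, with the block 0.00187), Cdk6 at -0.80 (0.0582, with the block 0.0251), Nampt at -0.74 (0.0886, with the block 0.0174) and Foxp1 at -0.76 (0.2, with the block 0.0263). The 2 that rose with the block were Cd44, a hyaluronan receptor, at 2.13 (adjusted p = 0.197, with the block 0.00219) and the anti-apoptotic gene Bcl2 at 1.03 (0.147, with the block 0.00751). A further probe of Cd44, of 5 tested, had the opposite sign. Sirt1 at -0.55 (adjusted p = 0.245) and Cdk4 at -0.16 (adjusted p = 0.814) passed in neither fit.

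Genes of the cell division cycle had the lowest list means of all lists tested. Of 37 genes of G1/S and DNA replication, 29 fell and 0 rose, and of 29 genes of G2/M and mitosis, 23 fell and 0 rose. Adjusted over the list alone, 33 and 27 fell. Mcm10, which acts at replication origins, fell 4.36-fold (log2 fold change -2.12, SE 0.33, adjusted p = 0.0152), and Mybl2, a transcription factor of proliferating cells, 3.26-fold (-1.71, SE 0.38, adjusted p = 0.0349), a call lost with no detection filter. Top2a, the topoisomerase that untangles replicated chromosomes, fell 4.37-fold (-2.13, SE 0.26, adjusted p = 0.0113), and the mitotic kinase gene Aurkb 4.64-fold (-2.21, SE 0.25, adjusted p = 0.011).

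Rpa2, for a single-stranded DNA binding protein, fell 4.01-fold and the mitotic kinesin gene Kif4 3.37-fold. The mean log2 fold change was -1.42 for G1/S and DNA replication (camera adjusted p = 6.08e-21) and -1.54 for G2/M and mitosis (camera adjusted p = 2.02e-17). Both calls were lost with an estimated correlation, at an adjusted p = 0.224 and an adjusted p = 0.258. The list medians in pairs 1, 2 and 3 were -1.63, -1.27 and -1.40 for the former and -1.99, -1.39 and -1.53 for the latter.

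DNA damage repair genes were lower too. Of 19 tested, 6 fell and 0 rose, adjusted over the list alone 10 fell, and 13 fell with the block. Fancd2, a central protein of interstrand crosslink repair, fell 3.05-fold (log2 fold change -1.61, SE 0.26, adjusted p = 0.0163), the helicase gene Blm 2.59-fold (adjusted p = 0.0484) and Brip1, for a helicase that binds BRCA1, 2.22-fold (adjusted p = 0.0314). The call of Blm was lost with cyclic loess or no detection filter (adjusted p up to 0.16 over all alternatives). Rad18, above background on 2 of 3 miR-34c arrays, was at -1.39 (adjusted p = 0.0569, with the block 0.00191). The mean was -0.88 (camera adjusted p = 8.14e-07, and adjusted p = 0.258 with an estimated correlation).

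**Figure D2:**
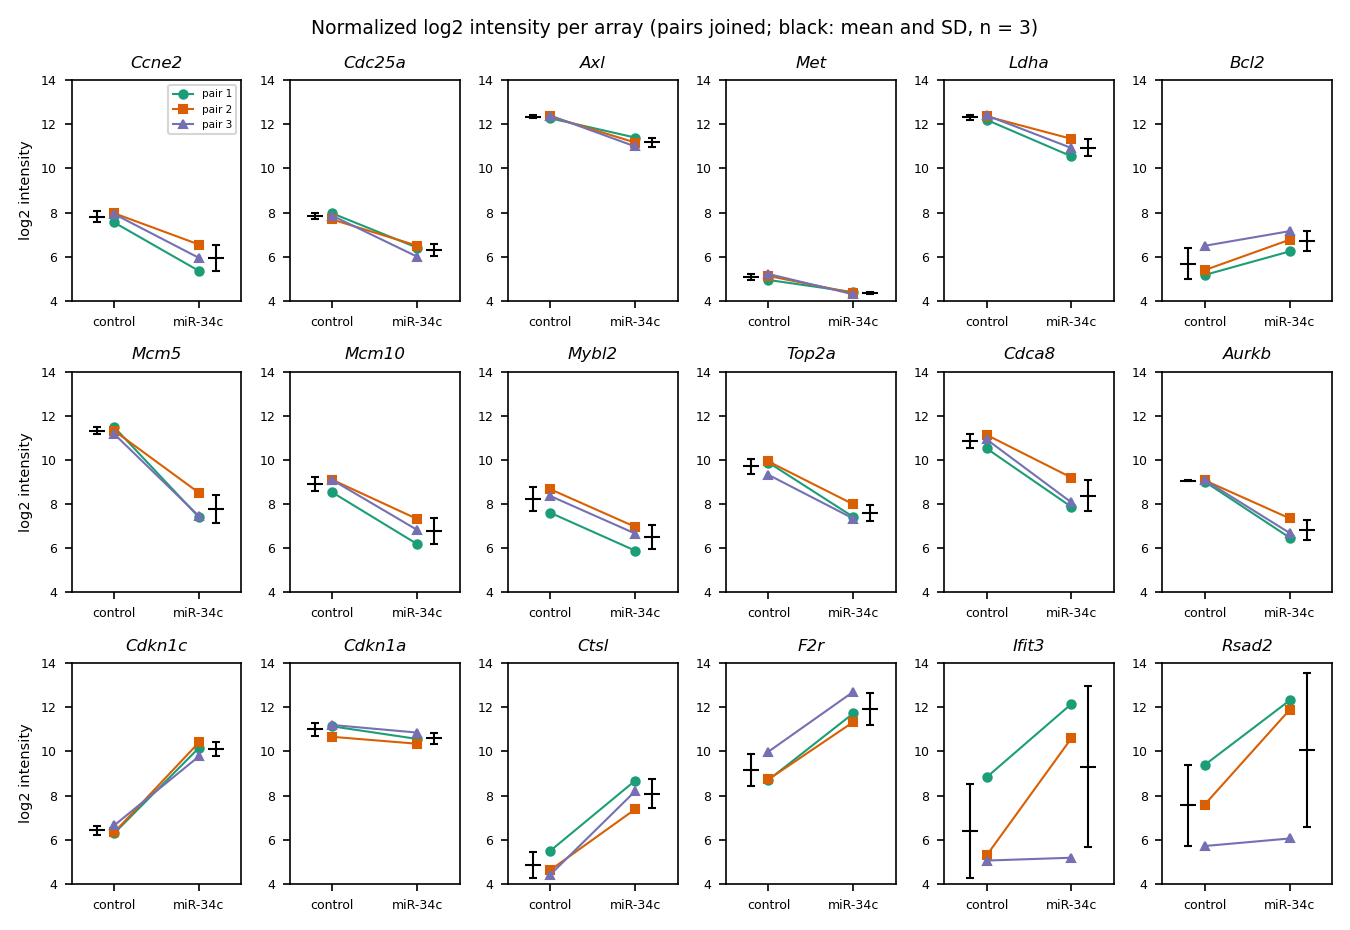
Normalized log2 intensity (vertical axis) of 18 genes in control and miR-34c samples, 1 marker per array, with lines joining same-numbered samples and black bars for the group mean and SD (n = 3). Ccne2, Cdc25a, Mcm5 and Top2a were lower in each pair and Cdkn1c higher, Ifit3 differed by 3.32 in pair 1 and 0.13 in pair 3, and Cdkn1a, chosen after its values were seen, had a log2 fold change of -0.41 (adjusted p = 0.291).

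Targets of p53 did not move as a list. Of 25 tested, 0 rose and 2 fell, and adjusted over the list alone 3 fell. Those called were Ei24, 2.38-fold lower (adjusted p = 0.0227), and Ccng1, for cyclin G1, 2.2-fold lower (adjusted p = 0.0335), and both calls were lost with median scaling (adjusted p up to 0.0831 and 0.0964 over all alternatives). With the block 3 rose and 7 fell, among them Xpc, for a DNA damage sensor, at 0.78 (adjusted p = 0.156, with the block 0.0162) and Gadd45a at 0.95 (0.216, with the block 0.0164). The list mean was -0.19 (camera adjusted p = 0.307).

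Apoptosis regulators went both ways. Of 20 tested, 2 rose and 2 fell, adjusted over the list alone 5 rose and 3 fell, and with the block 7 rose and 4 fell. The pro-survival gene Bcl2l2 rose 2.11-fold (adjusted p = 0.0167) and Birc2, for an inhibitor of apoptosis protein, 1.61-fold (adjusted p = 0.0453). The call of Birc2 was lost in 10 of 20 alternatives, including median scaling and the mean over its probes (adjusted p up to 0.271, log2 fold change down to 0.35), and that of Bcl2l2 with median scaling (0.0791). The pro-apoptotic genes Diablo and Casp9 fell 2.27-fold (adjusted p = 0.0286) and 2.12-fold (adjusted p = 0.0183). The list mean was 0.20 (camera adjusted p = 0.307). Among 11 genes of senescence and its secreted factors, Cdkn1c rose and Lmnb1, for lamin B1, fell 2.06-fold (adjusted p = 0.0269), also adjusted over the list alone. With the block 4 rose and 2 fell, including Igfbp3 at 1.20 (adjusted p = 0.505, with the block 0.00423) and Igfbp5 at -2.19 (0.122, with the block 0.00667). That list's mean was 0.40 (camera adjusted p = 0.629).

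Interferon response genes were higher with miR-34c in 2 of the 3 pairs. The list's median was 1.13 and 1.20 in pairs 1 and 2 and -0.09 in pair 3. Of 26 genes tested, 0 passed the test, over all genes or adjusted over the list alone, and 8 rose with the block. Ifit3, an interferon-induced antiviral gene, was at 2.92 (adjusted p = 0.357, with the block 0.0345), with 3.32, 5.31 and 0.13 in the pairs. Rsad2, for the antiviral enzyme viperin, was at 2.52 (0.397, with the block 0.0245), Usp18, above background on 2 of 3 control arrays, at 2.36 (0.326, with the block 0.0245) and the ubiquitin-like modifier gene Isg15, above background on 2 of 3 arrays of each group, at 1.99 (0.403, with the block 0.027). The mean of 0.93 passed with camera (adjusted p = 0.0269) and not with an estimated correlation (adjusted p = 0.79) or by fry (adjusted p = 0.45). The camera call was lost without control replicate 2 (adjusted p = 0.0699), control replicate 3 (0.109), miR-34c replicate 1 (0.261) or miR-34c replicate 2 (0.251), and on genes detected on all 6 arrays (0.523). With 1 array left out the mean ran from 0.47 to 1.69.

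NF-kB targets and inflammatory cytokines did not pass as a list (12 tested, mean 0.34, camera adjusted p = 0.347). None passed alone over all genes or adjusted over the list alone (0 up, 0 down), while with the block 3 rose and 1 fell. The chemokine genes Ccl7 and Ccl2 were at 1.63 (adjusted p = 0.114, with the block 0.00365) and 0.88 (0.215, with the block 0.0102), and the adhesion gene Vcam1 at 1.15 (0.295, with the block 0.00897). The macrophage growth factor gene Csf1 was at -1.18 (0.395, with the block 0.0132) and above background on 2 of 3 miR-34c arrays.

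Markers of cell identity did not pass as lists. Their counts are to be read beside all genes tested, of which 11.1% were called, and 31.1% with the block. Of 12 epithelial and serous tumour markers, Msln, for the surface protein mesothelin, rose 2.45-fold (log2 fold change 1.29, SE 0.31, adjusted p = 0.0454), and 0 passed adjusted over the list alone. This call was lost with median scaling or no detection filter (adjusted p up to 0.123 over all alternatives). With the block 3 rose, including the progesterone receptor gene Pgr at 0.66 (adjusted p = 0.173, with the block 0.0401) and the keratin gene Krt8 at 0.50 (0.116, with the block 0.0455). The mean was 0.27 (camera adjusted p = 0.307). Of 15 mesenchymal markers 0 changed, over all genes or adjusted over the list alone, and with the block 3 rose and 2 fell (mean 0.21, camera adjusted p = 0.536). The matrix genes Tnc and Col5a1 were at 1.91 (0.112, with the block 0.0013) and 0.88 (0.0602, with the block 0.0194), and Col6a1 at -1.93 (0.102, with the block 0.00254). Fn1, for fibronectin, was at 0.83 (0.582, with the block 0.0256), and 1 of its 3 probes had the opposite sign.

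Markers of other cell types that a tumour culture could hold were not called without the block. Smooth muscle markers (8 tested, mean -0.26), immune cell markers (3 tested, mean -0.19) and endothelial markers (3 tested, mean -0.34) each had a camera adjusted p = 0.629 and 0 members called, over all genes or adjusted over the list alone. With the block the smooth muscle gene Myl9, above background on 2 of 3 miR-34c arrays, at -0.97 (adjusted p = 0.338, with the block 0.00541) and the endothelial gene Esam at -0.83 (0.329, with the block 0.0197) fell. Of the ovarian granulosa markers Inhba, for an activin subunit, was at 2.06 (0.132, with the block 0.0168) and above background on 2 of 3 control arrays.

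Genes of miRNA processing were slightly lower as a list. Of 15 tested 0 passed alone, over all genes or adjusted over the list alone, and with the block 1 rose and 5 fell. The mean was -0.36 (camera adjusted p = 0.0401, and adjusted p = 0.258 with an estimated correlation). Tnrc6c, a partner of Argonaute, was at -0.80 (adjusted p = 0.221, with the block 0.0094), Ago2 itself at -0.55 (0.165, with the block 0.0358), the helicase gene Ddx17 at -0.66 (0.0569, with the block 0.0204) and Prkra at 0.61 (0.104, with the block 0.0243). The list's call was lost without control replicate 2 (adjusted p = 0.0689), control replicate 3 (0.0534), miR-34c replicate 2 (0.069) or miR-34c replicate 3 (0.0903), with median scaling (0.0518) or no background correction (0.0506), and on genes detected on all 6 arrays (0.129). With the block it was lost without pair 2 (0.0923) or pair 3 (0.0976).

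Ribosomal protein genes were also lower by a small amount. Of 18 tested, Rpl19 fell 1.82-fold (adjusted p = 0.0414, but up to 0.116 over 20 alternatives, with median scaling and cyclic loess among those that ended the call), 0 passed adjusted over the list alone, and 4 fell with the block, including Rplp0 at -0.70 (0.0876, with the block 0.0174). The mean was -0.27 (camera adjusted p = 0.0401, with the block 0.0642, and adjusted p = 0.434 with an estimated correlation). This call was lost without control replicate 1 (adjusted p = 0.0575), control replicate 2 (0.0699), miR-34c replicate 1 (0.0538) or miR-34c replicate 3 (0.11), with cyclic loess (0.0598), and on genes detected on all 6 arrays (0.0897). With the block it was also absent without pair 1 (0.065), pair 2 (0.12) or pair 3 (0.123).

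Signalling lists did not pass. Of 16 PI3K, Akt and FoxO genes, the regulatory subunit gene Pik3r1 rose 2.04-fold (adjusted p = 0.0341), also adjusted over the list alone, and with the block 5 rose and 1 fell, including the kinase gene Sgk1 at 1.75 (0.153, with the block 0.00215). The call of Pik3r1 was lost with median scaling (adjusted p up to 0.121 over all alternatives). The list's mean was 0.24 (camera adjusted p = 0.347). No gene of Notch (9 tested, mean -0.18, camera adjusted p = 0.77), Wnt (13 tested, mean -0.12, camera adjusted p = 0.629) or TGF-beta signalling (17 tested, mean 0.07, camera adjusted p = 0.875) was called, with 0 adjusted over the list alone. With the block 1 Notch gene fell, 1 Wnt gene rose and 2 fell, and 3 TGF-beta genes rose and 1 fell. They included the Notch target Hey1 at -1.13 (0.348, with the block 0.00693), the Wnt antagonist Sfrp1 at -1.48 (0.132, with the block 0.00573), the ligand Wnt7b at 1.89 (0.162, with the block 0.00655), Tcf7l1 at -1.23 (0.198, with the block 0.00499), the receptor Tgfbr2 at 0.81 (0.154, with the block 0.016) and the ligand Bmp4 at -1.16 (0.505, with the block 0.0135).

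Metabolic and stress lists were not called by camera without the block, where single genes were, and hypoxia targets were called with it. The glycolytic enzyme genes Aldoa, for aldolase A, and Ldha fell, Aldoa by 3.72-fold (log2 fold change -1.90, SE 0.23, adjusted p = 0.011). They were the 2 of 16 glycolysis genes called, also adjusted over the list alone, and with the block 2 rose and 5 fell, including Eno2 at 1.13 (0.41, with the block 0.00582). The glycolysis mean was -0.32 (camera adjusted p = 0.0808, but 0.0316 without control replicate 1 and 0.0139 with no detection filter). Of 13 hypoxia targets 0 were called, over all genes or adjusted over the list alone, and 5 fell with the block, including Ndrg1 at -1.76 (0.064, with the block 0.0013) and the angiogenic factor gene Vegfa at -1.06 (0.104, with the block 0.026). Their mean was -0.49 (camera adjusted p = 0.0612, with the block 0.0245). The list also passed without control replicate 1 (0.0316) or miR-34c replicate 2 (0.0342), with no detection filter (0.0139), and with the block without pair 1 (0.0287) or pair 2 (0.011). It did not pass with an estimated correlation (camera adjusted p = 0.34, with the block 0.649) or by fry (adjusted p = 0.0802, with the block 0.111).

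In the unfolded protein and integrated stress response, the stress-induced factor gene Atf3 rose 3.19-fold (adjusted p = 0.0135, above background on 1 of 3 control arrays). The serine and glycine synthesis genes Shmt2 and Phgdh fell 2.37-fold (adjusted p = 0.0181) and 1.75-fold (adjusted p = 0.035), and the call of Phgdh was lost in 9 of 20 alternatives, including median scaling (adjusted p up to 0.116). These were the 3 of 24 genes called, also adjusted over the list alone, with 3 up and 5 down with the block (mean 0.04, camera adjusted p = 0.842). No gene of cholesterol synthesis was called (15 tested, 0 adjusted over the list alone, mean -0.20, camera adjusted p = 0.39, but 0.0373 with the block and without pair 1). Of 8 imprinted and let-7 fetal genes Cdkn1c rose, also adjusted over the list alone, and with the block 2 rose and 1 fell, the latter Dlk1 at -1.22 (adjusted p = 0.395, with the block 0.0128, above background on 1 of 3 miR-34c arrays). That list's mean was 0.48 (camera adjusted p = 0.48, fry adjusted p = 0.0353, with the block 0.0619).

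**Figure D3:**
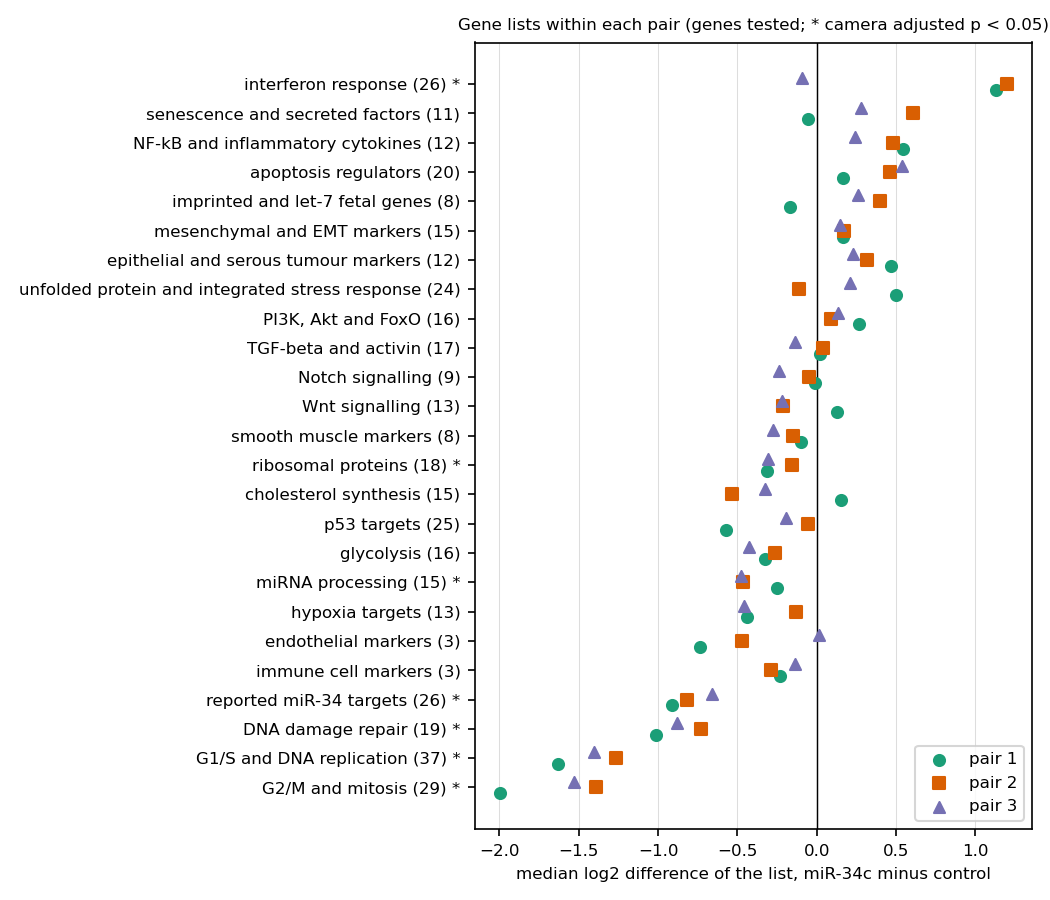
Median log2 difference (miR-34c minus control, horizontal axis) of the 25 gene lists tested (vertical axis, genes tested in brackets) within each same-numbered pair, 1 marker per pair. Asterisks mark the 7 lists called by camera at a preset correlation, 6 lower and 1 higher, of which 0 were called with an estimated correlation, and the G2/M medians lie between -1.99 and -1.39.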

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

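The comparison of probes without a gene symbol was chosen after the gene results were seen, and the count over other splits of the samples was planned.

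Probes that carried no gene symbol in the annotation stood outside the gene comparison, and some differed between the groups. Of 1891 such probes above background on at least 3 arrays, 159 changed in the same limma test, or 8.41%, with 49 higher and 110 lower with miR-34c. With the replicate block 512 changed. The share of 8.41% was below that among the genes tested, of which 11.1% changed, and 31.1% with the block. What these probes read was not examined, and no explanation was tested.

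The 969 changed genes were set against every other way of splitting the 6 samples into 3 and 3. Of the 10 splits, 1 gave as many genes, the real one, and the highest of the others gave 0. Among the 4 splits that part all 3 same-numbered pairs, the real one gave 2721 genes with the replicate block and the highest of the others 0. Each other split puts control and miR-34c arrays on both sides, so a difference between the groups adds to the spread within a side. This lowers its count, so that a count of 0 there is no measure of chance. With 10 splits a share under 0.05 cannot be reached.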

How the results depend on the processing

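Every alternative named here was planned, and the planned 3' UTR site search with its own alternatives was not run. The signs and camera calls of the cell cycle, DNA repair and miR-34 target lists held under each other background correction, normalization, filter, left-out array and left-out pair, with mean log2 fold changes of -0.75 to -0.42 for the targets. All of them lost their call with an estimated correlation. From 31.1% to 35.6% of the probes on an array were above background, so changes in weakly expressed genes are bounded at best.

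The 969 changed genes (443 up, 526 down) became 2721 (1414 up, 1307 down) with the replicate block. With the block and without pair 1 they were 2057 (1077, 980), without pair 2 2158 (1127, 1031) and without pair 3 1661 (865, 796). Leaving out 1 array without the block gave 1 to 506 genes, 1 to 217 up and 0 to 301 down, the lowest without control replicate 2, and the cause of that low count was not tested. Median scaling gave 510 (170 up, 340 down), so that 33.3% of the changed genes were higher in place of 45.7%. A plain t-test gave 0 genes after Benjamini-Hochberg adjustment (0 up, 0 down) and 1965 at an unadjusted p under 0.05 (933, 1032), where limma gave 2499. An adjusted p under 0.1 gave 1703 (833, 870). The other settings gave 913 to 1322 genes. The median log2 fold change of all genes moved by less than 0.1 under each scaling.

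The share of genes with 1 sign in all 3 pairs fell from 61.5% to 42.2% with no detection filter, which adds genes at background. Of 25 lists 7 were called, 4 with genes detected on all 6 arrays, 0 with an estimated correlation and 4 to 8 with 1 array left out. The block added hypoxia targets to the camera calls and ended the ribosomal one, and changed no other camera call. By fry it ended the calls of reported miR-34 targets (adjusted p = 0.00476, with the block 0.0547) and G2/M and mitosis (0.00762, with the block 0.0547). It also ended the fry calls of miRNA processing (0.0117, with the block 0.0619) and imprinted and let-7 fetal genes (0.0353, with the block 0.0619).

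Lists that were not called turned their sign as follows, and the cause was not tested. With 1 array left out the mean ran from -0.18 to 0.54 for mesenchymal markers, -0.44 to 0.0035 for smooth muscle, -0.58 to 0.18 for immune cells, -0.19 to 0.020 for Wnt, -0.066 to 0.16 for TGF-beta, -0.10 to 0.16 for the unfolded protein response and -0.32 to 0.027 for cholesterol synthesis. The Wnt mean was 0.015 without pair 3. TGF-beta was at -0.0071 with median scaling, -0.10 with detection on all 6 arrays and -0.054 without shared members. The unfolded protein response was at -0.11 without pair 1, -0.052 with median scaling, -0.020 with detection on all 6 arrays and -0.019 with array weights. Cdk4, not called, ran from -0.43 to 0.18 with 1 array left out and was at 0.047 without pair 1.

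Of the 24 genes with the largest changes, 17, 1 and 18 were still called without control replicates 1, 2 and 3, and 16, 20 and 22 without miR-34c replicates 1, 2 and 3. All 24 kept their sign, for which they had been picked on the same arrays. Among the genes of the other observations, median scaling ended the calls of Hexa, Tpp1 and H2bc4, and no detection filter that of H2bc4 (adjusted p up to 0.115, 0.073 and 0.101 over all alternatives).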

Other observations

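The cilium, lysosome and histone lists, and the tests of array brightness, quantile normalization, Cdkn1a and cells in S phase, were chosen after the ranked genes had been seen. Background, normalization, the multiciliated programme and near-identical histone copies were given their tests before the measured value was known.

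Genes of cilia were higher with miR-34c, in part through the genes that prompted these lists. Of 78 tested in 3 groups, 30 rose and 0 fell, and with the block 49 rose and 1 fell. Of 24 genes of intraflagellar transport 9 rose (18 with the block), and of 29 of the BBSome and transition zone 11 (18 with the block). Of 25 genes of the motile axoneme 10 rose, but among the 16 not already seen in the highest ranks 1 rose, and with the block 4 rose and 1 fell, with a mean of 0.18 (camera adjusted p = 0.339). The 25 were those of 71 on the array that passed the detection filter. A gene at background on every control array passed only if detected on all 3 miR-34c arrays. For such a gene a rise was partly a condition of being tested. This held for Nme5 and Dnaaf3, and for Ttc26, Wdpcp and Fuz of the other groups. Ift88, a core subunit of the intraflagellar transport complex, rose 5.2-fold (adjusted p = 0.011). Dync2li1 and Wdr60, of the motor that returns cargo from the ciliary tip, had log2 fold changes of 2.36 and 1.87, and the kinesin gene Kif3a 1.33. Rsph9, a radial spoke gene, rose 4.71-fold and the transition zone gene B9d1 was at 1.96. Dnah11 was at -1.27 (adjusted p = 0.0513, with the replicate block 0.00581). The mean over all 78 was 0.89 and lay between 0.56 and 0.91 under the other corrections and normalizations. With an estimated correlation the 78 genes had a camera adjusted p = 0.047, the intraflagellar transport genes and the BBSome and transition zone genes an adjusted p = 0.0635 each, and the 55 genes not seen in the highest ranks an adjusted p = 0.11.

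Lysosomal genes were higher as well. Of 54 tested, 21 rose and 0 fell, and with the block 40 rose, with a mean of 0.81 (camera adjusted p = 0.031 with an estimated correlation) and 0.66 to 0.85 under the other corrections and normalizations. Atp6v0a1, a subunit of the acidifying proton pump, rose 3.53-fold, the calcium channel gene Mcoln1 had a log2 fold change of 1.29, the peptidase gene Tpp1 1.19 and the hexosaminidase gene Hexa 1.10. Leaving out the genes already seen among the highest ranks, 42 remained, of which 9 rose and 0 fell, and with the block 28 rose (mean 0.61, camera adjusted p = 0.022 with an estimated correlation).

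The fall of cell cycle genes was weighed against technical explanations. The miR-34c array was dimmer than its control in pair 1 (mean raw intensity -62.0) and brighter in pairs 2 and 3 (11.4 and 5.90). The median over 66 cell cycle list entries was -1.78, -1.30 and -1.45, where array brightness was expected to give the pairs different signs. These medians were taken after quantile normalization, which removes differences of brightness between arrays, so they do not weigh against brightness. With median scaling in place of quantile normalization the pair means were -2.18, -1.16 and -1.36, which argues against the normalization as the whole cause. Cdkn1a, through which raised p53 activity could act, had a log2 fold change of -0.41, with an upper 95% limit of 0.13, under 0.58. This gene and its bound were chosen after its values were seen, so the outcome was known beforehand. The values show no rise of Cdkn1a that large and do not decide on p53 activity. A biological effect of the miR-34c transfection, the difference the design names, stays open and was not tested further.

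The rise of cilium genes was weighed in the same way, on the 55 genes not already seen among the highest ranks, of which 7 rose and 0 fell, and with the block 26 rose and 1 fell (mean 0.49). Noise of probes near background is argued against by the 38 of these detected on all 6 arrays, whose mean was 0.48, 0.39 and 0.56 in the pairs. Under the other corrections and normalizations the mean of the 55 was 0.31 to 0.51. A multiciliated programme cannot be told apart from its absence by Foxj1, Mcidas, Gmnc and Ccno. They were detected on 0 miR-34c arrays but also on at most 1 control array, so that probes unable to read them would give the same. Of the 5 other regulators tested (mean -0.73, camera adjusted p = 0.016, and adjusted p = 0.17 with an estimated correlation) 2 fell, and 3 with the block. Cep152 (-1.19) and Plk4 (-1.20, above background on 1 of 3 miR-34c arrays) also serve centriole duplication in dividing cells and so do not decide it. Rfx2 was at -1.10 (adjusted p = 0.166, with the block 0.00519, above background on 2 of 3 miR-34c arrays). Its fall goes against such a programme but is that of 1 gene called with the block alone, so the question stays open. A biological effect of miR-34c on these genes stays open and was not tested further.

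Replication-dependent histone genes moved apart, with 10 of 13 H2A genes lower and 0 higher (11 and 2 with the block, H2ac15 at -2.17 and H2ac18 at 2.71, the latter with an adjusted p = 0.069, with the block 0.0135), and 7 of 10 H2B genes higher and 0 lower (H2bc4 at 2.31). Of 18 H3 and H4 genes 16 lay below 0 (mean -0.61, camera adjusted p = 0.0023, fry adjusted p = 0.065), 0 were called and 5 fell with the block, their pair medians were 0.00075, -0.79 and -0.58, and with an estimated correlation the adjusted p was 0.17 for H2A, 0.20 for H2B and 0.22 for H3 and H4. The family means of -1.10 for H2A and 0.91 for H2B kept their sign under the other scalings but rest on the genes that prompted the lists, since 3 other H2A genes had a mean of 1.37 and 5 other H2B genes 0.19, with pair medians of 1.18, 0.06 and -0.59. Fewer cells in S phase stays open for the lower H2A genes and for the H3 and H4 genes. In pair 1, where the cell cycle genes were lowest (-1.78), H3 and H4 genes ran from -0.99 (H3c1) to 0.77 (H4c8). Their median of 0.00075 there does not decide it. The expectation that fewer such cells would lower the H2B genes too was not met (medians over all 10 in the pairs 1.29, 1.23 and 0.95). Which histone transcripts the labelling read was not examined, so the 7 higher H2B genes do not decide it either. A probe reading every copy of a family alike is argued against by the SD of the log2 fold changes within the H2A and H2B families, at least 0.98, but probes that read some of the copies stay open.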
